A study of Mus musculus with 2 samples.

How the data were processed

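The data are small RNA sequencing libraries from mouse helper T cells, 1 library from cells cultured as a control (Th0) and 1 from cells cultured toward the Th17 state, the interleukin-17-producing lineage. Per the labels, naive CD4+CD62L+ T cells came from the spleen of female C57BL/6 mice. Total RNA was extracted with a column kit for small RNA, libraries were made with the TruSeq small RNA chemistry, constructs of 140 to 150 bp were purified from a gel, and sequencing was on an Illumina HiSeq instrument. The labels state that profiling was done in triplicate, but the files analysed here hold 1 column of reads per group, and replicates are not analysed here. How any replicates were combined is not given in the sources used here.

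For each library the authors deposited a table of mature miRNAs with the name of the miRNA, its precursor or precursors, a read count and a TPM value. The deposited counts are whole numbers of reads per mature miRNA and are not normalized. The deposited TPM values are the same counts divided by a single total per library and a fixed scale factor, which was tested on the files: for miRNAs with at least 1000 reads the implied total was the same to within 0.0108 reads. These totals were 9072995 reads for Th0 and 13070648 for Th17, more than the listed counts add up to. The genome build was mm10, per the submitters' processing notes. The trimming tool, the aligner, the miRNA annotation release, the mismatches allowed and the treatment of reads that match several miRNAs are not given in the sources used here.

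Counts were used for all comparisons. A miRNA listed for 1 library and not for the other was taken as 0 reads in the other, since the smallest listed count was 1. Listed reads totalled 8358010 for Th0 and 11975371 for Th17. Counts were scaled to library size (CPM) with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.00 for Th0 and 0.997 for Th17. The log2 ratio of Th17 over Th0 was computed with 0.5 CPM added to both values. Folds and intervals were computed from the counts without that addition. The 95% interval of each ratio is exact and conditional on the sum of both counts (Clopper-Pearson). PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only, and they leave out the spread between cultures and the error of the scaling. With 1 library per group no test of the conditions is possible, and no p-value is given. The main rule, fixed before the data were examined, took miRNAs with a mean of at least 10 CPM, a ratio of at least 2-fold and an interval that excludes 1.

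Among the 298 miRNAs with a mean of at least 10 CPM, the median width of the interval to either side was 0.13 on the log2 scale, and 129 miRNAs had less than 0.1. Between 10 and 20 CPM the median was 0.37. These 298 miRNAs held 99.9% of the listed reads of each library. The procedure was tested on simulated data for the Th17 over Th0 comparison, with Poisson counts for the same miRNAs and 200 of them changed. Of 293 simulated miRNAs above the minimum, 53.9% of the intervals held the true ratio as computed and 94.9% did so once the error of the scaling, -0.098 on the log2 scale, was removed. The rule found 100% of the 40 miRNAs changed 3-fold, 100% of the 40 changed 4-fold, 48.7% of the 39 changed exactly 2-fold and 0 of the 95 unchanged miRNAs. The simulation had no spread between cultures, so the 0 does not measure false calls in the real libraries. Its coverage and scaling error belong to this setting, in which the 200 miRNAs were changed 1.5- to 8-fold in both directions.

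The 25 lists of miRNAs were fixed before the data were examined and held 182 distinct miRNAs, of which 168 were listed in at least 1 library. For each list with at least 3 members at 10 CPM or more, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean CPM in 10 bins. This percentile describes these 2 libraries and is not a test of the conditions, and miRNAs of a shared primary transcript are not independent. Some lists share members, so results of different lists are not independent either. The share of 5p reads among 5p and 3p reads was computed for each precursor with at least 100 such reads in each library, with exact binomial (Clopper-Pearson) intervals, joining precursors that share a mature miRNA. A shift was counted at 10 percentage points with intervals that do not overlap.

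The miRNAs named in the report were chosen by a rule fixed before the data were examined. They are the 10 largest and 10 smallest log2 ratios at a mean of at least 100 CPM with an interval excluding 1, the 5 most abundant miRNAs of each library, up to 4 members of each list with the largest absolute log2 ratio, and a fixed set of 18. Other miRNAs are named only where the text says they were chosen after their values were seen. Positions are those of GENCODE M21, whose assembly GRCm38 is the same as mm10. Of 782 precursors in the files, 774 had a gene in that annotation, 26 of them through a RefSeq synonym. Host genes are those that span the precursor on the same strand.

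The alternatives were scaling by total counts, by DESeq2 1.42.0 size factors or by the total without the 10 most abundant miRNAs of either library, no minimum or a minimum of 100 CPM, a 3-fold rule, the whole interval beyond 2-fold, summed arms, 5 CPM added in place of 0.5, summed counts per list, and a minimum of 1000 reads for arms. Scaling by the totals implied by the TPM values was added after the data were examined. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots.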

Results

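Small RNA libraries were compared between control Th0 cells and cells cultured under Th17 conditions, with 1 library per group. Both cultures started from naive CD4+CD62L+ T cells of mouse spleen in medium with 10% serum. Th0 medium held anti-CD28 at 1 µg/ml with anti-IL-4 and anti-IFN-γ at 5 µg/ml each. Th17 medium held the same antibodies plus anti-IL-2 and anti-IL-12 at 5 µg/ml each, TGF-β at 2 ng/ml, IL-6 at 40 ng/ml, IL-1β at 10 ng/ml and IL-23 at 40 ng/ml, and the Th17 culture lasted 6 to 7 days. The length of the Th0 culture is not given in the sources used here, so a difference in culture time cannot be separated from the Th17 conditions in any ratio below. The Th0 library listed 986 miRNAs with 8358010 reads and the Th17 library 1012 miRNAs with 11975371 reads. Each library here is 1 column of reads per group, and how the triplicates stated in the labels were combined is not given in the sources used here. Every interval given is therefore a 95% interval of counting error within these 2 libraries. Whether a difference exceeds the spread between cultures could not be tested.

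The first question was which miRNAs dominate each library. miR-21a-5p, a miRNA induced by T cell activation, was the most abundant in both, with 15.3% of the listed reads in Th0 (exact binomial interval 15.29 to 15.34%) and 15.0% in Th17 (15.02 to 15.06%). In Th0 it was followed by miR-92a-3p at 9.76%, miR-27b-3p at 9.75%, miR-191-5p at 7.36% and miR-22-3p at 6.24%. In Th17 it was followed by miR-27b-3p at 10.6%, miR-22-3p at 7.53%, miR-191-5p at 6.84% and miR-142a-5p at 6.59%, and miR-92a-3p stood at 4.90%. The 10 most abundant miRNAs took 68.7% of the Th0 reads (68.62 to 68.68%) and 66.2% of the Th17 reads (66.17 to 66.23%), and 9 of the 10 were shared.

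The second question was which miRNAs differ between Th17 and Th0 cells. miR-10b-5p, encoded in the Hoxd cluster, had the largest ratio among miRNAs with a mean of at least 100 CPM: 59.2 CPM in Th0 and 2619 CPM in Th17, 44.3-fold higher (interval 40.5 to 48.5). miR-147-3p, a miRNA known to be induced by inflammatory signals in macrophages, was 10.4-fold higher (10.0 to 10.9), from 258 to 2697 CPM. miR-155-5p, which promotes Th17 differentiation in mice, was 2.23-fold higher (2.21 to 2.24) and reached 31846 CPM. In the other direction miR-20b-5p, reported to restrain Th17 differentiation, was 7.66-fold lower in Th17 (7.13 to 8.23), from 582 to 76.1 CPM. miR-19a-3p was 6.49-fold lower (5.87 to 7.19) and miR-19b-3p 5.85-fold lower (5.68 to 6.03). Of 298 miRNAs with a mean of at least 10 CPM, 20 were at least 2-fold higher in Th17, 39 were at least 2-fold lower, and 239 (80.2%) met neither rule. The median log2 ratio over the 298 was -0.071.

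**Figure D1:**
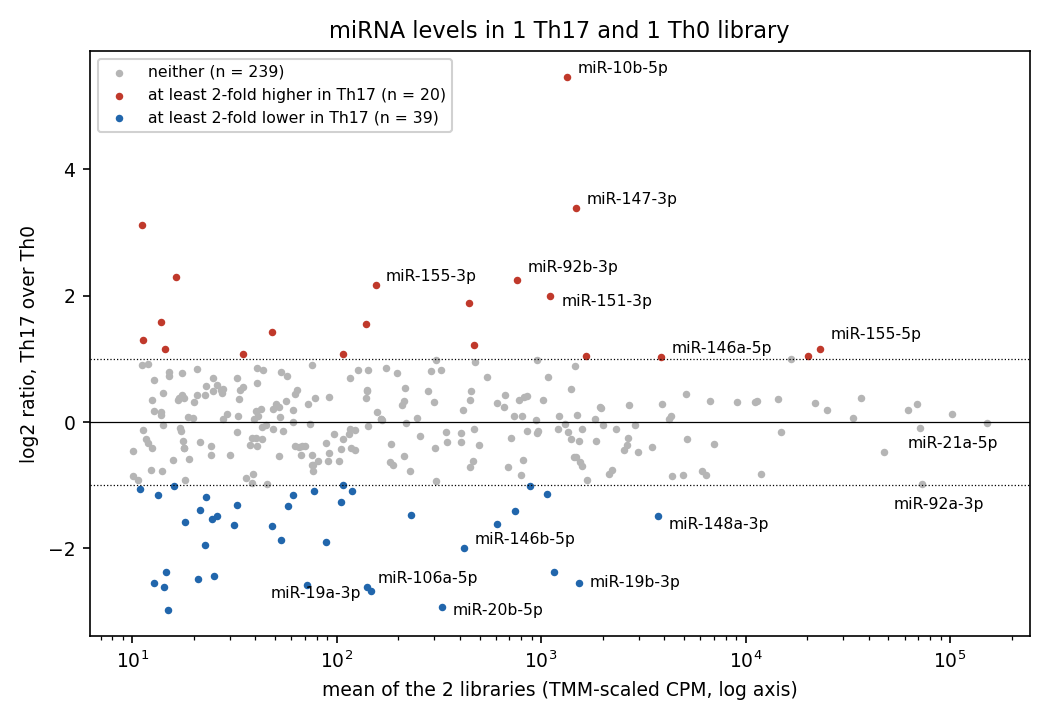
Log2 ratio of Th17 over Th0 against the mean TMM-scaled CPM of both libraries (log axis) for the 298 miRNAs with a mean of at least 10 CPM; each point is a miRNA and the dotted lines mark 2-fold. miR-10b-5p (5.46) and miR-147-3p (3.38) lie far above the other abundant miRNAs, while miR-20b-5p (-2.93), miR-19a-3p (-2.68), miR-106a-5p (-2.62) and miR-19b-3p (-2.55) lie lowest among those with at least 100 CPM.

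The remaining members of the 10 largest ratios at 100 CPM or more were miR-92b-3p, 4.76-fold higher in Th17 (4.56 to 4.98), miR-155-3p, 4.53-fold (4.11 to 5.01), miR-151-3p, from 441 to 1760 CPM (interval of the fold 3.86 to 4.14), miR-151-5p, 3.71-fold (3.52 to 3.92), miR-210-5p, 2.95-fold (2.70 to 3.24), miR-28a-3p, 2.34-fold (2.23 to 2.45), and miR-1948-3p, 2.12-fold (1.93 to 2.33). Both arms of the Mir155 hairpin and both arms of the Mir151 hairpin were among the 10. The remaining members of the 10 smallest were miR-106a-5p, 6.21-fold lower in Th17 (5.61 to 6.88), miR-363-3p, 5.17-fold lower (5.00 to 5.34), miR-146b-5p, 3.98-fold lower (3.78 to 4.19), miR-149-5p, 3.08-fold lower (2.96 to 3.20), miR-148a-3p, 2.82-fold lower (2.78 to 2.86), miR-18a-5p, 2.78-fold lower (2.61 to 2.96), and miR-20a-5p, 2.65-fold lower (2.56 to 2.74).

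In mm10 coordinates, Mir10b lies on chromosome 2 from 74726070 to 74726137, plus strand, within introns of the Hoxd3 and Hoxd4 gene models. Mir147 lies on the same chromosome from 122640803 to 122640881, plus strand, overlapping an exon of AA467197. Mir155 lies on chromosome 16 from 84714140 to 84714204, plus strand, overlapping an exon of its noncoding host Mir155hg. Mir151 is in an intron of Ptk2 on chromosome 15 (73254815 to 73254882, minus strand), and Mir92b is on chromosome 3 (89227116 to 89227198, minus strand) with no annotated host on its strand. Mir20b (52742113 to 52742192), Mir106a (52742503 to 52742567) and Mir363 (52741693 to 52741767) lie together on the minus strand of chromosome X outside annotated hosts. Mir19a lies on chromosome 14 from 115044000 to 115044081, plus strand, overlapping an exon of Mir17hg, the host transcript of the Mir17 cluster. miR-19b-3p and miR-92a-3p are each listed with a precursor in both clusters, so their reads cannot be divided between chromosomes 14 and X. How near-identical members of these clusters, such as miR-20a and miR-20b or miR-19a-3p and miR-19b-3p, were separated is not given in the sources used here.

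The Mir17 cluster, which drives proliferation of lymphocytes, and its X-linked paralog, the Mir106a cluster, were lower in Th17. All 9 measured members of the Mir17 list had intervals below 0, and 6 were at least 2-fold lower. Its median log2 ratio of -1.16 was at percentile 0.035 of the random lists, whose central 95% ran from -0.68 to 0.44. The members differed from each other: miR-19a-3p and miR-19b-3p had log2 ratios of -2.68 and -2.55, miR-18a-5p and miR-20a-5p of -1.47 and -1.40, miR-17-5p of -1.14 and miR-92a-3p of -0.98. All 6 members of the Mir106a list were at least 2-fold lower, with log2 ratios from -2.93 for miR-20b-5p to -2.37 for miR-363-3p. The other members named were miR-106a-5p, miR-18b-5p at -2.59 and miR-363-5p at -2.43. The median of -2.51 was below all 10000 random lists. In the Mir106b cluster, a further paralog within the Mcm7 gene, 5 of 6 members had intervals below 0 and none reached 2-fold. miR-106b-5p (-0.84) and miR-93-5p (-0.82) were the lowest and the median of -0.22 was at percentile 27.0. In the same cluster miR-106b-3p was at -0.25 and miR-25-5p at -0.19.

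**Figure D2:**
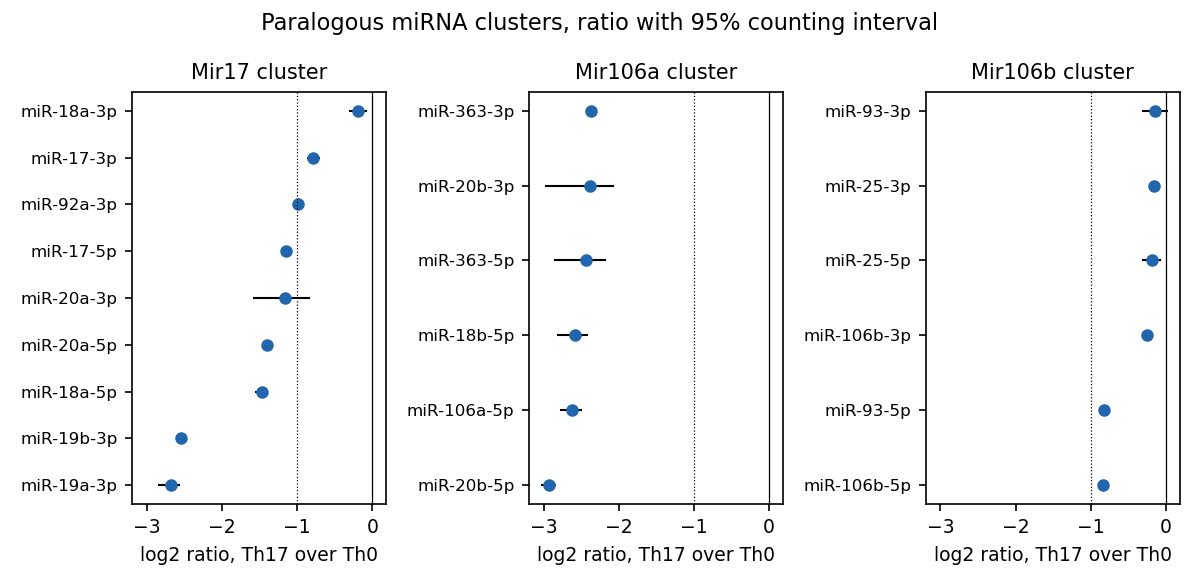
Log2 ratio of Th17 over Th0 (horizontal axis) for the members of 3 paralogous clusters with a mean of at least 10 CPM; points are the ratio in this pair of libraries, horizontal bars the 95% counting interval, and the dotted line marks 2-fold lower. Mir106a members lie between -2.93 and -2.37, Mir17 members spread from -2.68 to -0.19, and Mir106b members lie between -0.84 and -0.14.

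miRNAs with published roles in Th17 cells went both ways. Of 14 measured miRNAs listed as Th17-promoting, 7 had intervals above 0 and 7 below, with 1 at least 2-fold higher (miR-155-5p) and 2 at least 2-fold lower (miR-19b-3p and miR-17-5p). let-7e-5p in this list was 1.77-fold higher (1.63 to 1.93). Their median log2 ratio was 0.035 at percentile 61.4, and their mean was -0.12. miR-326-3p was 1.11-fold higher (1.04 to 1.20), miR-183-5p 1.06-fold higher (1.05 to 1.08) and miR-182-5p 1.14-fold higher (1.13 to 1.14), while miR-301a-3p was 1.12-fold lower (1.09 to 1.15) and miR-96-5p 1.72-fold lower (1.55 to 1.91). miR-21a-5p had a log2 ratio of -0.017 (-0.021 to -0.014). Under DESeq2 scaling it and miR-425-5p, named after its values were seen, moved above 0, to 0.052 and 0.022. Of 11 measured miRNAs listed as Th17-restraining, 2 had intervals above 0 and 9 below, with a median of -0.42 at percentile 5.90, while their summed CPM was 1.14-fold higher in Th17. Without miR-26a-5p, the most abundant member, named after its values were seen, the sum was 1.186-fold lower (1.178 to 1.194). miR-146a-5p, a negative regulator of NF-κB signalling, was the member that was at least 2-fold higher, at 2.04-fold (2.00 to 2.07), and it fell below 2-fold when the 10 most abundant miRNAs were left out of the scaling total (log2 ratio 0.959). miR-20b-5p and miR-18a-5p were at least 2-fold lower, and they are also in the Mir106a and Mir17 lists. miR-30a-5p was 1.63-fold lower (1.56 to 1.70), miR-27a-3p 1.81-fold lower (1.79 to 1.84), miR-10a-5p 1.29-fold lower (1.27 to 1.31) and miR-210-3p 1.04-fold lower (1.02 to 1.06). The direction of miR-210-3p, which is also in the activation-induced list, flipped under DESeq2 scaling, to 0.015 on the log2 scale.

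Of 15 miRNAs abundant in naive T cells, 11 had intervals above 0 and 4 below, with a median of 0.32 at percentile 96.0 and 1 member at least 2-fold higher. That member was miR-29a-3p, at 2.05-fold (2.04 to 2.07), which also fell below 2-fold without the 10 most abundant in the scaling total (log2 ratio 0.972). The naive T cell list shares 3 members each with the let-7, miR-30 and miR-29 families and 1 with the miR-181 family, given below. miR-181a-5p, which tunes T cell receptor sensitivity, was 1.99-fold higher (1.98 to 2.01) and miR-150-5p 1.25-fold higher (1.24 to 1.26), whereas miR-342-3p was 1.78-fold lower (1.76 to 1.81). miR-29b-3p was 1.77-fold higher (1.68 to 1.87). Of 15 measured activation-induced miRNAs, 2 were at least 2-fold higher, 5 at least 2-fold lower and 8 met neither rule, with a median of -0.15 at percentile 21.0. Its lower members included miR-146b-5p, miR-19a-3p, miR-18a-5p and miR-20a-5p. Of its 16 members, 5 are also in the Mir17 list and 6 in the Th17-promoting list. Of 10 measured TGF-β and Treg-linked miRNAs, 2 were at least 2-fold higher (miR-10b-5p and miR-146a-5p) and 1 was at least 2-fold lower (miR-146b-5p). Members below 10 CPM, named after their values were seen, all had intervals above 0. They were miR-99a-5p with 1 read in Th0 and 29 in Th17, miR-125b-5p with 4 and 62, and miR-100-5p with 23 and 82. This list had a median of -0.096 at percentile 40.0 and a mean of 0.26.

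Among smaller clusters, all 4 members of the Mir132 cluster, which responds to cAMP signalling through CREB, had intervals above 0, with a median of 0.50 at percentile 89.7. miR-132-3p was 1.43-fold higher (1.40 to 1.47) and miR-212-3p 1.31-fold higher (1.27 to 1.36), and miR-132-5p and miR-212-5p were 1.42-fold and 1.41-fold higher. In the Mir221 cluster 3 of 4 members were below 0, led by miR-221-3p at 1.62-fold lower (1.59 to 1.66) and miR-221-5p at 1.61-fold lower (1.45 to 1.78). miR-222-3p had a log2 ratio of -0.15 and miR-222-5p of 0.092, and the median of -0.42 was at percentile 21.0. The Mir183 cluster had 2 members above 0, 1 below and 1 whose interval spanned 0 (miR-183-3p), with a median of 0.083 at percentile 65.5 and a mean of -0.11. The Mir23a and Mir23b clusters had 3 members above 0, 4 below and 2 whose interval spanned 0, with a median of 0.035 at percentile 56.4 and a mean of -0.079. Their named members went both ways, with miR-27b-5p at 0.81, miR-23a-3p at -0.47 and miR-24-2-5p at -0.60 on the log2 scale.

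Among families, all 9 members of the let-7 family had intervals above 0, none by 2-fold, with a median of 0.26 at percentile 86.6. When the 10 most abundant miRNAs were left out of the scaling total, let-7d-5p, let-7f-5p and miR-98-5p, named after their values were seen, moved to -0.023, -0.00030 and -0.020. Examples were let-7a-5p at 0.33, let-7g-5p at 0.32 and let-7i-5p at 0.30. The miR-29 family had a median of 0.82 at percentile 95.5, with miR-29c-3p on the lower side at -0.62. The miR-181 family had a median of 0.37 at percentile 89.3, with miR-181b-5p at 0.71, miR-181c-5p at -0.27 and miR-181d-5p at 0.025, whose interval spanned 0. The miR-15/16 family had 5 of 6 members below 0 and a median of -0.73 at percentile 3.69. Within it miR-195a-5p was 8.98-fold lower (6.30 to 13.1) and miR-497a-5p 6.80-fold lower (4.89 to 9.63). Both were at or below 27.1 CPM, with 36 and 44 reads in Th17. Mir497 (70234717 to 70234800) and Mir195a (70235042 to 70235135) lie side by side on the plus strand of chromosome 11. Their ratios may therefore not be independent. miR-15b-5p was 1.78-fold lower (1.74 to 1.81) and miR-15a-5p 1.55-fold lower (1.51 to 1.58). The miR-30 family had 2 members above 0 and 3 below, with a median of -0.11 at percentile 38.3, while their summed CPM was 1.09-fold higher in Th17. Without miR-30d-5p, the most abundant member, the sum was 1.10-fold lower (1.09 to 1.11). Members of this family included miR-30d-5p at 0.37, miR-30c-5p at 0.28 and miR-30e-5p at -0.34. Of 10 measured miRNAs from the Sfmbt2 intron, 1 was above 0, 6 below and 3 spanned 0, with a median of -0.34 at percentile 31.6. miR-467a-5p was at -0.44, miR-467c-5p at -0.53, miR-467e-5p at -0.52 and miR-669b-5p at -0.46. For the imprinted Dlk1-Dio3 locus 1 of 30 listed members reached a mean of 10 CPM over both libraries, miR-127-3p, which was 1.99-fold lower (1.73 to 2.28).

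Markers of cells other than T cells differed by list. The myeloid marker miR-223-3p was at 3.34 CPM in Th0 and 6.78 CPM in Th17, 2.03-fold higher (1.31 to 3.24). The erythroid miRNA miR-451a was at 0.716 and 2.01 CPM. miR-486a-5p and miR-486b-5p had nearly equal counts (1360 and 1361 reads in Th0), so they are uncertain as separate miRNAs. Both were at 162 CPM in Th0 and 167 CPM in Th17, and both intervals spanned 0. Of the stromal and endothelial list, the endothelial miRNAs miR-126a-3p and miR-126a-5p were 3.17-fold lower (2.65 to 3.81) and 2.01-fold lower (1.84 to 2.20), while 4 of its 7 listed members, all with a mean over both libraries below 10 CPM, had intervals above 0. Of 6 measured epithelial markers 5 had intervals below 0 and 2 were at least 2-fold lower, with a median of -0.68 at percentile 7.11. miR-200b-3p was 3.76-fold lower (3.37 to 4.20), miR-200a-3p 2.98-fold lower (2.44 to 3.65) and miR-429-3p 1.97-fold lower (1.69 to 2.28), and miR-200c-3p was 1.38-fold higher (1.16 to 1.65). In the list linked to B cells and myeloid progenitors all 3 members had intervals above 0: miR-99b-5p was 2.06-fold higher (2.01 to 2.11), from 1081 to 2226 CPM, miR-125a-5p 1.35-fold higher (1.30 to 1.40) and miR-125b-5p, named after its values were seen, 10.9-fold higher on 4 and 62 reads. miR-99b-5p fell below 2-fold when the 10 most abundant miRNAs were left out of the scaling total (log2 ratio 0.976). No liver, muscle or neural marker reached a mean of 10 CPM over both libraries, and the 6 listed ones summed to 14.1 CPM in Th0 and 6.11 CPM in Th17. That fall came from miR-9-5p, named after its values were seen, with 116 reads in Th0 and 57 in Th17. Without it the sum was higher in Th17, on few reads (ratio of Th0 over Th17 0.18, interval 0.020 to 0.76).

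The third question was whether the arm taken from each hairpin differed. Of 173 precursors with at least 100 reads in each library, 4 shifted by at least 10 percentage points, all of them toward the 3p arm in Th17. They are named after their values were seen. The 5p share of Mir219a-1 was 38.2% in Th0 (32.0 to 44.7%) and 14.7% in Th17 (11.1 to 19.0%), on 238 and 333 reads. The 5p share of Mir18 (mir-18a) was 73.4% (71.9 to 74.8%) and 53.1% (51.2 to 55.0%). The 5p share of Mir700 was 67.1% (63.3 to 70.7%) and 50.4% (48.0 to 52.8%), and that of Mir106b was 56.9% (56.1 to 57.7%) and 46.8% (45.9 to 47.6%).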

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

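The deposited TPM values imply a read total per library that is larger than the sum of the listed counts. The difference is 714985 reads in Th0, or 7.88% of that total, and 1095277 reads in Th17, or 8.38%. These reads stand out because they belong to the authors' totals and to no miRNA in the tables, and what they are was not analysed here. Scaling by those totals, an alternative chosen after the data were examined, gave the same 20 miRNAs at least 2-fold higher, and 40 at least 2-fold lower: the 39 of the main comparison and miR-92a-3p.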

How the results depend on the processing

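Scaling by total counts gave the same 20 higher and 39 lower miRNAs. Scaling by the totals behind the TPM values, chosen after seeing the data, gave the same 20 higher and 40 lower, the 39 and miR-92a-3p. DESeq2 scaling gave 24 higher, including the 20, and 35 lower, all among the 39, and those lost included miR-126a-5p. The total without the 10 most abundant gave 17 and 43, of which 17 and 39 were shared, and the 3 higher miRNAs lost were miR-146a-5p, miR-29a-3p and miR-99b-5p. The count of higher miRNAs was 62 with no CPM minimum, 13 at 100 CPM and 8 at 3-fold, and that of lower miRNAs 92, 15 and 20 under the same settings. A looser minimum admits more miRNAs and a stricter rule admits fewer by construction. Summing the arms of each precursor gave 14 and 33. With the whole interval beyond 2-fold, 16 and 31 remained, and with 5 CPM added 17 and 34 remained. The share of the 10 most abundant miRNAs was 65.3% in Th0 and 63.4% in Th17 without miR-21a-5p. At 1000 reads, 2 of 115 precursors shifted arms. The Mir17 and Mir106a lists lay outside the central 95% of random lists under every alternative run for lists, joined by the Th17-restraining list at 100 CPM (percentile 1.54) and the naive T cell list with summed counts (percentile 99.0). Among 92 named miRNAs, DESeq2 scaling reversed miR-21a-5p to 0.052 and miR-210-3p to 0.015 on the log2 scale. This scaling moved ratios up by about 0.069, and both miRNAs had been just below 0. Why the scalings differ was not tested. Against the main scaling, the named log2 ratios moved up by at most 0.069 with DESeq2 and down by at most 0.066 with the total without the 10 most abundant. The direction of ratios within about 0.1 of 0 is therefore not secure against the choice of scaling. For ratios of any size, the spread between cultures is not measured. The depth limits miRNAs below 10 CPM most. No paired analysis was possible because each group has 1 column of reads, and no replicate could be left out.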

Other observations

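The tests on miR-10b-5p, on paralog reads, on GC content and on RNA from other cells below were chosen after their values were seen, as were the low-level miRNAs grouped as non-T and the arms, paralogs and locus members named as examples. The drift test was fixed before its result was seen, but the pattern that it addresses had been seen by then. A depth test, also fixed before its result was seen, thinned the Th17 reads and was left out, because a ratio scaled to library size does not change with thinning on average. A first GC test, fixed before its result was seen, removed a linear trend. It was replaced because that trend was too shallow to move the members by more than 0.0431 from their mean shift. Earlier paralog tests, which compared arms taken as free of near-identical paralogs, were left out because those arms are within 3 mismatches of an X-linked precursor over some stretch of 20 bases.

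Members of the imprinted Dlk1-Dio3 locus were mostly too low for the main rule but lay on the same side. Of 30 listed members, 29 had a lower CPM in Th17, 12 had a counting interval wholly below 0 and 0 had an interval above 0. Their summed reads were 2.41-fold lower in Th17 (2.18 to 2.67), from 125 to 51.7 CPM, and 3.03-fold lower (2.60 to 3.53) without miR-127-3p, the most abundant member. Members with more than a few reads included miR-541-5p, with 84 reads in Th0 and 26 in Th17, and miR-410-3p, with 64 and 20. The paralogs miR-193a-3p and miR-193b-3p moved apart: miR-193a-3p was at 35.8 CPM in Th0 and 5.95 CPM in Th17, and miR-193b-3p at 5.25 and 27.6 CPM.

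The 2 arms of a hairpin often differed in their ratio. Over 68 precursors with at least 100 reads of each arm in each library, the log2 ratios of the major and minor arm correlated across precursors (Pearson 0.72, Spearman 0.66; precursors are not independent replicates). In 45 of them the counting intervals of the arms did not overlap, with the minor arm above in 23 and below in 22, and in 11 the arms had opposite signs with both intervals excluding 0. miR-210-3p was at -0.055 and miR-210-5p at 1.56, miR-30e-5p at -0.34 and miR-30e-3p at 0.96, miR-142a-5p at 0.18 and miR-142a-3p at -0.92, and miR-155-5p at 1.15 and miR-155-3p at 2.17. No explanation was tested for these differences.

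miR-10b-5p was 44.3-fold higher in Th17. If it were a fixed share of misassigned reads of the near-identical miR-10a-5p, its share of their joint reads would not differ between libraries, but it was 1.95% in Th0 (1.79 to 2.13%) and 53.3% in Th17 (52.8 to 53.7%). Stromal or endothelial RNA would bring its own abundant miRNAs, and the largest gain among listed markers, that of miR-199a-3p, was 0.418% of the gain of miR-10b-5p. The gain of miR-223-3p, abundant in neutrophils, monocytes and macrophages, was 0.135% of it. These values argue against misassigned miR-10a-5p reads at a fixed share and against stromal or endothelial RNA. For neutrophils, monocytes and macrophages they rest on miR-223-3p alone. miR-147-3p, known to be induced by inflammatory signals in macrophages, rose from 258 to 2697 CPM, so macrophages are not excluded. Other cells are not excluded either: miR-99b-5p, from the list linked to B cells and myeloid progenitors, gained 44.8% as much as miR-10b-5p. However, miR-99b-5p was already at 1081 CPM in Th0, and which cells supplied its gain cannot be told from these libraries. Mir99b, Mirlet7e and Mir125a lie within the same gene, Spaca6, on chromosome 17. The ratios of miR-99b-5p, let-7e-5p and miR-125a-5p are therefore not independent. A hypothesis that stays open is that the Th17 culture itself may raise miR-10b-5p in T cells, which 1 library per group cannot separate from a difference between cultures or in their length.

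Members of the Mir17 cluster were lower in Th17 by unequal amounts, although they share a host transcript. The GC content of the side of the precursor that holds the arm ran from 40.5 to 50% over the 9 members. Of 6 pairs of members within 1 GC point, 5 had counting intervals that did not overlap: miR-17-5p and miR-19b-3p, with the same GC content, differed by 1.40 on the log2 scale, and miR-18a-3p and miR-20a-3p by 0.97. Of the 5 pairs, 3 include miR-19b-3p or miR-92a-3p, whose reads cannot be divided between chromosomes 14 and X, and the other 2 both rest on miR-18a-3p. The intervals cover counting error only, and the arms of a hairpin were also apart in 45 of 68 precursors. The pairs therefore show that members with near-equal GC content of the precursor side differed beyond counting error in these 2 libraries. They do not decide whether GC content is a cause. GC content of the mature arms was not analysed here. Reads of the X-linked paralogs, whose 6 list members had log2 ratios from -2.93 to -2.37, cannot be excluded. Each arm of mir-17, mir-18a, mir-19a and mir-20a had a stretch of 20 bases on its precursor side with 1 to 3 mismatches to the same side of an X-linked precursor, and the mismatches allowed in mapping are not given in the sources used here. Unequal maturation or turnover of the members may contribute, and no biological explanation was tested.

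The stromal, erythroid and myeloid miRNAs of the lists with a mean below 10 CPM, 10 in all, summed to 57 reads in Th0 and 453 in Th17. The sum was 5.58-fold higher (4.23 to 7.49), and 7 of them had an interval above 1. The limit of 10 CPM leaves out miR-486a-5p and miR-486b-5p, whose intervals spanned 0, and miR-126a-3p and miR-126a-5p, which were lower. With all listed members summed, the stromal and endothelial list was 1.70-fold lower in Th17 (1.58 to 1.83). The erythroid list was 1.04-fold higher (log2 interval -0.015 to 0.13) and the myeloid list 2.08-fold higher. The group of 10 also leaves out other lists. Over all 6 lists of markers of other cells or tissues, the 18 miRNAs with a mean below 10 CPM summed to 179 and 589 reads. That sum was 2.31-fold higher (1.95 to 2.75), with 8 intervals above 1. miR-9-5p, a neural marker, had an interval below 1, with 116 and 57 reads. Of these 18, miR-223-3p is also listed as Th17-promoting and miR-214-3p as activation-induced. miR-125b-5p is also listed as TGF-β and Treg-linked and miR-124-3p as Th17-restraining. These miRNAs are therefore not specific to other cells in the lists used here. The median log2 ratio of 243 other miRNAs with a mean below 10 CPM and at least 20 reads was 0.0071 (5th to 95th percentile -1.55 to 1.82), which argues against a general drift of low counts. A trace of RNA from other cells may contribute. The 4 stromal miRNAs with at least 20 reads, miR-143-3p, miR-199a-3p, miR-199a-5p and miR-214-3p, were 8.54- to 16.3-fold higher. Their counting intervals overlap over 1.78 on the log2 scale. With 1 to 10 reads each in Th0 these intervals are wide, so their overlap decides nothing. miR-145a-5p, below that minimum, had 1 read in each library. Such a trace cannot be told apart from low expression in the cultured T cells, because miR-199a and miR-214 share a locus and the counts are few. In addition, miR-9-5p and the endothelial miRNAs miR-126a-3p and miR-126a-5p were lower in Th17.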
